A study of Mus musculus with 8 samples.

How the data were processed

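Cardiac ventricles were taken from 8 mice aged 4.5 months, 4 control (Ctrl) and 4 double knockout (DKO) animals. All carried loxP-flanked alleles of the transcription factor genes Sox5 and Sox6. DKO animals also carried Cre recombinase under the αMHC promoter, which is active in cardiomyocytes, and Ctrl animals lacked Cre. Per the labels' protocols, the atria were removed, RNA was extracted with Trizol, and single-end Illumina libraries were made with a TruSeq kit.

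The authors aligned reads with TopHat2 2.0.9 to the mouse build mm9 and used Cufflinks 2.1.1 and Cuffdiff 2.1.1, per the submitters' processing notes. The gene annotation and the settings of these tools are not given in the sources used here. The 5 deposited tables hold genes, isoforms, transcription start site groups, coding sequences, and a subset of 642 genes past a fold of 1.3. Each holds 1 FPKM value per genotype, per the file headers, so the authors' FPKM values are pooled over the animals of a genotype. They carry no error per animal. The authors' p-values and q-values come from their Cuffdiff comparison, per the file headers. The smallest deposited p-value was 5e-05, and 385 called genes carried it, so the q-values do not rank those genes. The q-values equalled Benjamini-Hochberg adjustment over the 12133 tested genes to within 5.18e-07. The deposited log2 fold change, per the file headers, sets Ctrl over DKO, so every log2 value here was recomputed from the authors' FPKM values as DKO over Ctrl. In the subset, the recomputed and deposited log2 values differed by at most 9.72e-06 apart from the sign. Genome positions are in mm9 and are written counting from 1. The reads per library and their depth are unknown here, so no interval of an FPKM value or fold and no detection floor was computed.

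A gene was called when the authors' Cuffdiff test marked it at a q of at most 0.05. No test across animals was run for this work, because the tables hold no value per animal. What was computed here concerns gene lists. The 49 lists covered pathways, cell types and tissue handling, and were fixed before the data were examined, as were the tests of these lists, the rule for naming genes and all alternatives except the 3 that the closing section marks as chosen later. Of these, 46 had at least 3 tested members. Called members were compared with the other tested genes by a two-sided Fisher's exact test, separately for higher and lower genes, with Benjamini-Hochberg adjustment over 92 comparisons. Genes are not independent replicates, so this test describes the calls. The median log2 of each list was also placed among 10000 random lists of the same size, matched on mean FPKM in 10 bins. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the authors' p-values of the list's members. On simulated data with 12133 genes, the Fisher test found 20 of 20 lists in which 8 of 20 members were made higher, and 1 of 100 random lists. The simulated members were drawn independently. The simulation therefore gives neither the detection of smaller shares nor an error rate for lists whose genes move together.

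Named genes followed a fixed rule. It took Sox5, Sox6 and their paralog Sox13, the 10 called genes with the largest and the 10 with the smallest log2 ratio, and up to 4 called members per list with the largest change. It also took the 3 members with the highest FPKM in lists with no call, and the 5 called genes with the highest FPKM. A called gene needed an FPKM of at least 1 in its higher group. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen. Alternatives covered the q and fold thresholds, FPKM filters, pseudocounts, a rescaling of the groups, other backgrounds and other feature levels. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.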

Results

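RNA from the ventricles of 4 DKO and 4 Ctrl mice was compared to learn how the adult heart muscle differs when Sox5 and Sox6, which encode SoxD transcription factors, are deleted in cardiomyocytes. The series title names pressure overload, and the labels give no operation for these 8 animals. The gene table lists 23100 loci, of which Cuffdiff tested 12133. All levels below are the authors' FPKM values, 1 per genotype, and the folds were computed from them.

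Sox6 was lower in DKO, at 1.69 against 3.39 FPKM in Ctrl, a log2 ratio of -1.01 with a q of 0.00158 in the authors' deposited table. In the mm9 build, Sox6 lies on chromosome 7 at 122614858 to 123182258. Its most abundant isoform in Ctrl was at 0.896 FPKM in DKO and 2.20 in Ctrl. Sox6 isoforms that Cuffdiff did not test went both ways, among them 0.703 against 0.348 FPKM and 1.70e-04 against 0.851 FPKM. Sox5, on chromosome 6 at 143776945 to 144158088, was at 0.497 FPKM in DKO and 0.369 in Ctrl, and Cuffdiff did not test it. Sox13, the SoxD gene that was not targeted, was at 9.41 and 8.96 FPKM, with a q of 0.887 in the authors' deposited table. Cre acts in cardiomyocytes, so other ventricular cells keep both targeted genes. The Sox5 values therefore do not check the label of that gene, and the gene totals do not separate deleted from intact exons.

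Ventricles of DKO mice had higher levels of cardiac stress, matrix, complement and macrophage genes, and lower levels of genes for fatty acid oxidation, the respiratory chain and ion channels. The authors' deposited table called 893 genes, 522 higher and 371 lower in DKO. The median fold was 1.49 among higher genes and 1.32 among lower genes. A fold of at least 2 was reached by 66 higher and 22 lower genes. The higher genes with the largest folds at loci without a small RNA were Hspa1b, a heat shock protein (7.13-fold, from 1.54 FPKM in Ctrl), the matrix protein gene Tnc (6.21-fold, 1.15 against 0.185 FPKM, a log2 of 0.86 with 1 FPKM added to both) and Gdf15, a secreted stress factor (6.09-fold, 9.32 against 1.53 FPKM). Hspa1a was 5.36-fold higher, Gm1821 3.96-fold and Clec7a, a receptor of phagocytes for fungal glucans, 3.34-fold (1.55 against 0.464 FPKM). Hspa1a and Hspa1b are near-identical copies, as are Lyz1 and Lyz2, and how the authors' model split their shared reads is not given in the sources used here, so their single values are uncertain.

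**Figure D1:**
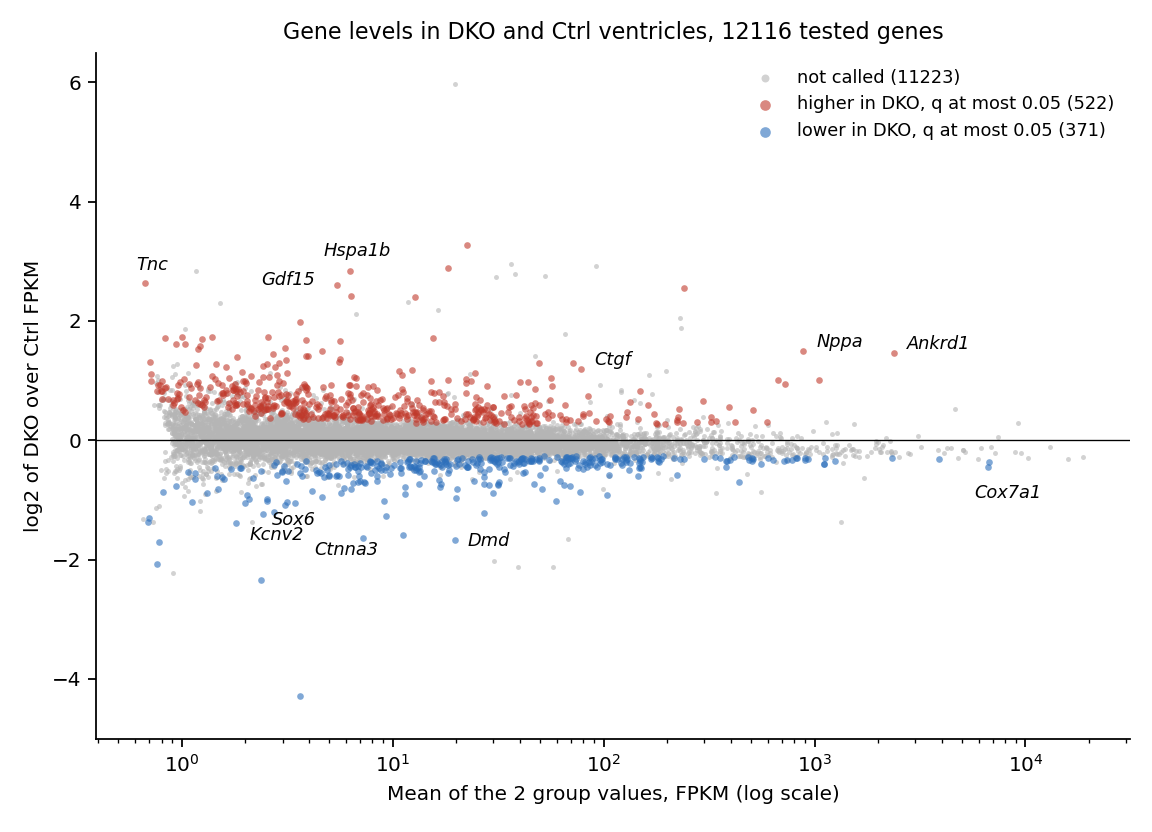
Log2 of DKO over Ctrl FPKM (y axis) against the mean of the 2 group values (x axis, log scale) for the 12116 tested genes above 0 in both groups, with 1 uncalled gene beyond the y axis. Red points are the 522 genes called higher and blue points the 371 called lower in the authors' deposited table.

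Among the genes with large falls, Dmd, which encodes dystrophin, was 3.17-fold lower (9.41 against 29.8 FPKM), and Ctnna3, the catenin of the intercalated disc, 3.02-fold lower (5.56 against 16.8 FPKM). Pfkfb1, an enzyme that regulates glycolysis, was 3.11-fold lower, the Wnt inhibitor gene Wif1 2.60-fold, the mitochondrial peptidase gene Immp2l 2.40-fold and the potassium channel subunit gene Kcnv2 2.34-fold. Large falls were also listed for 2210407C18Rik (5.08-fold), Helt (0.294 against 1.23 FPKM) and Cngb3 (3.24-fold). Dmd, Ctnna3 and Immp2l each had a listed locus of over 500 kb. In this class, to which Sox6 also belonged, 14 of 92 tested genes were lower and 1 was higher. Each of these genes had a q of at most 0.05 in the authors' deposited table. Among the 5 called genes with the highest level, Ankrd1, a stress-responsive muscle protein gene, was 2.75-fold higher (3483 against 1267 FPKM). The other 4 were mitochondrial and lower, namely Slc25a4 (5871 against 7591 FPKM), Cox7a1 (5597 against 7641 FPKM), Atp5g3 (3485 against 4305 FPKM) and Cox6a2 (2091 against 2565 FPKM).

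The remaining loci with large rises each join a small RNA shorter than 200 bases with a longer gene. In each, the small RNA was listed at 0 in Ctrl and had no test result from Cuffdiff. The Rcan3 locus with Mir700 was 9.69-fold higher, but its longer transcript was at 4.50 and 4.18 FPKM. The Rabggtb locus with Snord45c was 5.85-fold higher, and its longer transcripts were at 71.0 and 70.2 FPKM. The 1810032O08Rik locus with Snord1a was 5.32-fold higher, and its longer transcripts were at 3.88 and 4.06 FPKM. The Dnaja1 locus with Mir207 was 7.36-fold higher, and its longer transcripts, those of a heat shock co-chaperone, were at 6.34 and 4.36 FPKM (1.45-fold).

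Of the 46 gene lists tested, 10 held more higher genes and 4 more lower genes than the other tested genes did, by Fisher's exact test after adjustment over 92 comparisons. In the cardiac stress and fetal program, 15 of 22 members were higher and none lower (adjusted exact p = 1.56e-14), or 18 adjusted over the list alone. Besides Tnc, Gdf15 and Ankrd1, the protease inhibitor gene Serpina3n was 3.30-fold higher (23.9 against 7.25 FPKM) and Nppa, which encodes atrial natriuretic peptide, 2.81-fold (1303 against 464 FPKM). Chosen after their values were seen, Nppb was 2.01-fold and Acta1 2.02-fold higher, while Myh7, the slow myosin heavy chain gene, was not called at 287 against 246 FPKM.

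Genes of the fibroblast matrix rose together, with 30 of 39 tested members higher and none lower (adjusted exact p = 6.18e-32), or 35 adjusted over the list alone. Ltbp2, a matrix protein of microfibrils, was 2.89-fold higher, Ctgf, a matricellular protein gene, 2.29-fold (108 against 47.3 FPKM) and Thbs1 2.19-fold. Of the fibroblast markers, 9 of 15 were higher (adjusted exact p = 2.87e-08), or 14 adjusted over the list alone. They included Mfap5 (1.67-fold), Col3a1 (1.51-fold) and Col1a2 (1.49-fold). Mfap5, Col3a1, Col1a2, Dcn, Col1a1 and Lum also stand in the matrix list, and Tnc, Ctgf, Postn and Cilp in both the stress and matrix lists. The results of these lists therefore share genes. Basement membrane genes held 1 higher gene, Col4a3, and 1 lower gene, Sgca, of 19 tested. In TGF-beta and BMP signaling, 5 of 28 were higher (adjusted exact p = 0.0411), or 6 adjusted over the list alone, among them Gdf15, Tgfb2 (1.71-fold) and Fstl1 (1.44-fold). That value became 0.0985 with calls of at least 1.3-fold and 0.139 with members found in 1 list only.

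Macrophage markers were higher in 14 of 20 tested members (adjusted exact p = 5.89e-14), or 19 adjusted over the list alone. Ccr2, a chemokine receptor of monocytes, was 3.00-fold higher (1.82 against 0.607 FPKM), Mpeg1 2.65-fold and Lyz2, the lysozyme gene of myeloid cells, 1.77-fold (189 against 107 FPKM). Complement genes were higher in 12 of 16 (adjusted exact p = 1.27e-12), or 14 adjusted over the list alone, with C3 at 42.0 against 25.1 FPKM. C1qa, C1qb and C1qc stand in both the macrophage and complement lists. The stress, matrix, fibroblast, macrophage and complement lists still passed with members found in 1 list only. Cytokine and chemokine genes were higher in 6 of 19 (adjusted exact p = 9.52e-04), or 9 adjusted over the list alone, led by Ccl8 (3.18-fold), Lcn2 (2.49-fold) and Ccl2 (1.90-fold). Interferon-stimulated genes held 1 higher gene, Ifit2, and 3 lower genes, Iigp1, Gbp4 and Gbp7, of 30 tested. Endothelial markers held no called gene of 16, with a median log2 of -0.05, and red cell and platelet markers held none of 7, with a median of 0.02. Of smooth muscle markers, only Acta2 was called among 13, at 1.25-fold higher.

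**Figure D2:**
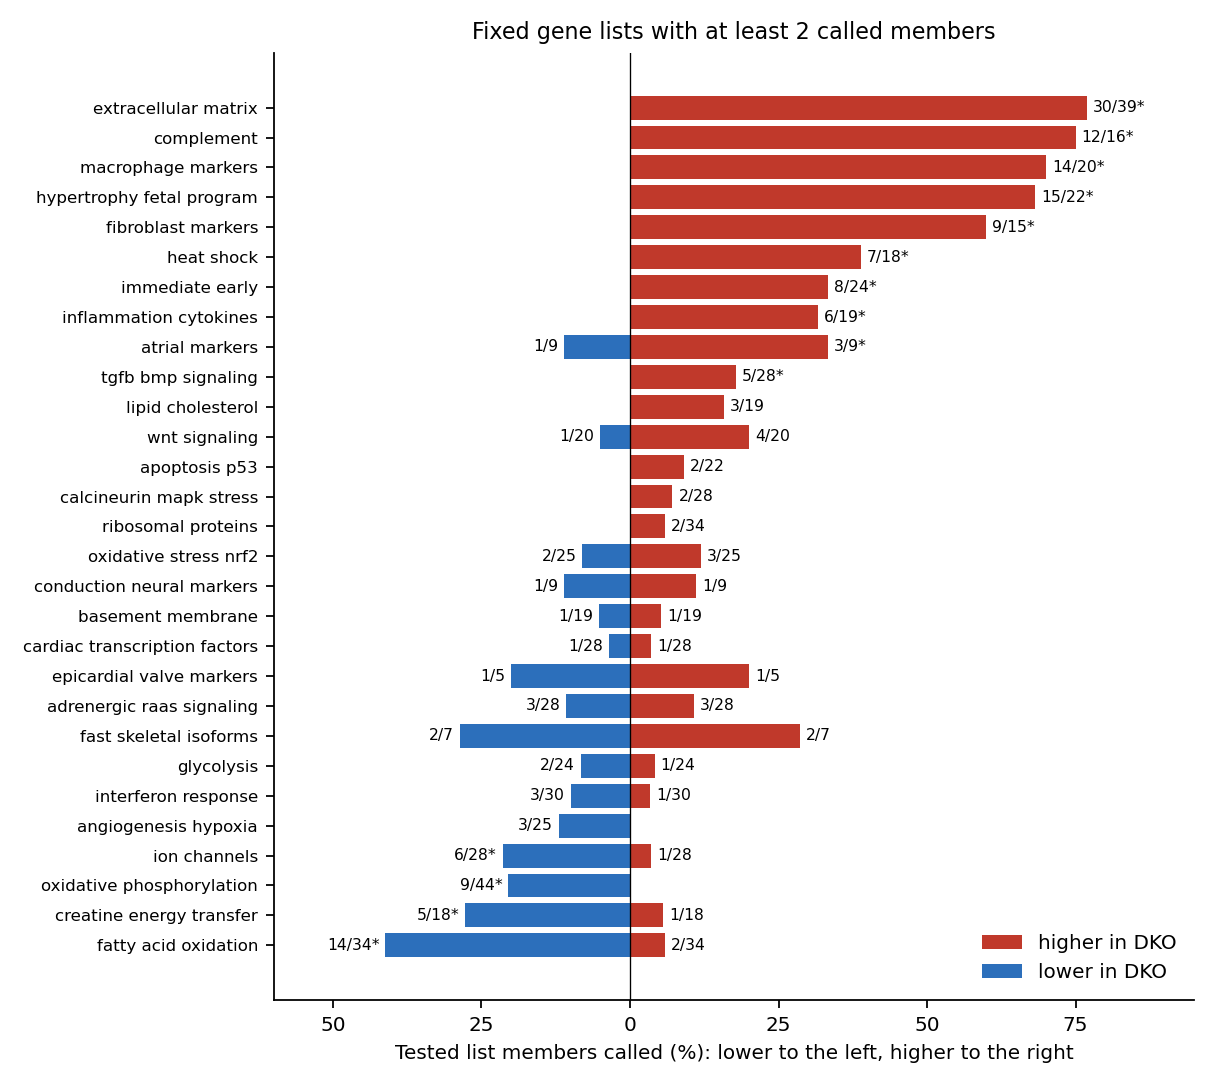
Percent of tested members called higher (red, to the right) and lower (blue, to the left) in DKO for the 29 fixed lists with at least 2 called members. Fractions give called over tested members, and a star marks an adjusted exact p under 0.05 by Fisher's exact test, as for the 30 of 39 matrix genes.

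Genes of fatty acid uptake and oxidation were lower in 14 of 34 members (adjusted exact p = 7.20e-12), or 21 adjusted over the list alone. Eci1 (320 against 439 FPKM) and Hadh (479 against 632 FPKM), enzymes of beta-oxidation, were 1.37-fold and 1.32-fold lower, and Acot1 was 1.85-fold lower. In the same list Angptl4, an inhibitor of lipoprotein lipase, was 1.63-fold higher, and 1 other gene, Pdk4, was higher, chosen after its values were seen. Nuclear genes of the respiratory chain had log2 ratios below 0 in 44 of 44 members, of which 9 were called lower (adjusted exact p = 5.96e-05), or 21 adjusted over the list alone. Uqcrc1 was 1.32-fold and Sdhb 1.23-fold lower. Among creatine kinase and TCA cycle genes, 5 of 18 were lower (adjusted exact p = 0.00128), or 11 adjusted over the list alone, among them Suclg1 (1.28-fold) and Sucla2 (1.26-fold), and Ckb was 1.37-fold higher. Cardiomyocyte markers, none called, had log2 ratios below 0 in 12 of 12 members with a median of -0.20, beside medians of -0.26, -0.21 and -0.26 in these 3 lists. With calls of at least 1.3-fold the respiratory chain list had an adjusted exact p of 0.548 with 2 genes and the creatine and TCA list 1.0 with 0 genes. Glycolysis genes held 1 higher gene, Hk1, and 2 lower genes, Pfkfb1 and Slc2a4, of 24 tested.

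Among cardiac sodium, potassium and pacemaker channels, 6 of 28 were lower (adjusted exact p = 0.00128), or 7 adjusted over the list alone. Kcnv2 and Kcnd2, a channel of the transient outward current (1.63-fold, 5.58 against 9.09 FPKM), were lower. Of the calcium handling genes, only Cacna1h, a T-type calcium channel gene, was called among 21, at 3.07-fold higher (1.41 against 0.460 FPKM), while 18 of the 21 had log2 ratios below 0, with a median of -0.18, and 2 were lower adjusted over the list alone. Adult sarcomere genes held no called gene of 24, with Myl2 at 17014 against 20639 FPKM, Actc1 at 12506 against 13546 and Tpm1 at 9245 against 11309. Their log2 ratios were below 0 in 17 of the 24, with a median of -0.11. Of the junction genes, only Ctnna3 was called among 15. Atrial markers were higher in 3 of 9, Nppa, Dkk3 and Pam, and lower in 1, Kcnj3 (adjusted exact p = 0.0388 for higher genes). That value was 0.191 against genes at an FPKM of at least 1 in both groups, 0.524 with the 4 members found in 1 list only and, in an alternative chosen after seeing the data, 0.213 without genes spanning over 200 kb.

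**Figure D3:**
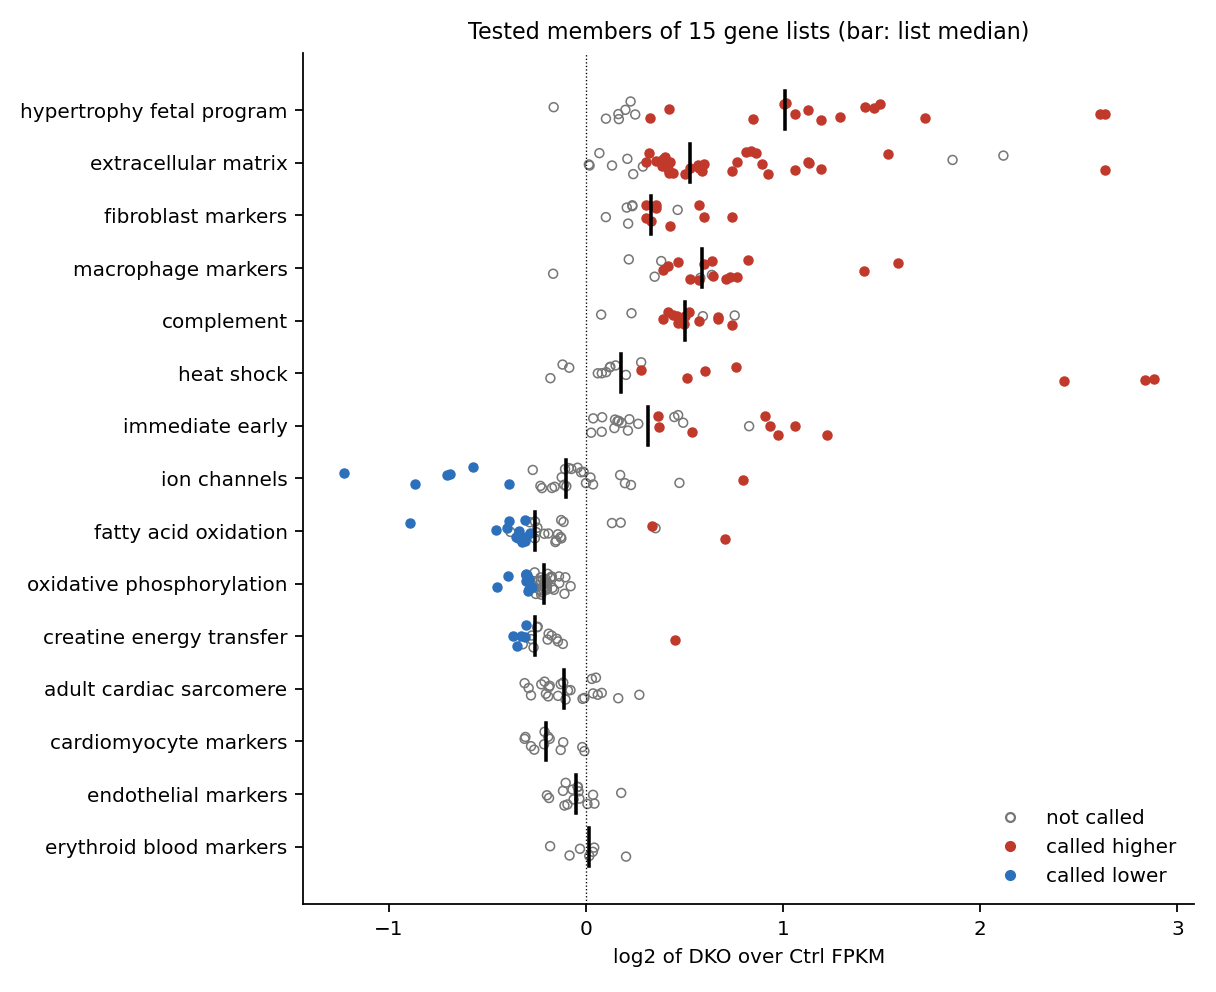
Log2 of DKO over Ctrl FPKM (x axis) of each tested member of 15 fixed lists, with filled points for genes called higher (red) or lower (blue) and a bar at each list's median. Matrix members have a median of 0.53 and fatty acid oxidation members a median of -0.26.

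Lists that respond to stress or handling also held higher genes. Heat shock genes were higher in 7 of 18 (adjusted exact p = 5.96e-05), or 7 adjusted over the list alone, with Hsph1 1.69-fold higher. Without Dnaja1, whose locus holds a small RNA, 6 of 17 were higher (adjusted exact p = 5.01e-04). Chaperones of the endoplasmic reticulum held no called gene of 24, with Hspa5 at 254 against 268 FPKM. Immediate-early genes were higher in 8 of 24 (adjusted exact p = 5.84e-05), or 14 adjusted over the list alone, led by Myc (2.34-fold), Nr4a3 (2.08-fold), Nr4a1 (1.96-fold) and Egr2 (1.91-fold). Only Per2 was called among 19 clock genes, at 1.43-fold higher. Sex-linked genes held no called gene of 7, and the Y-linked genes Eif2s3y (60.9 against 59.1 FPKM) and Ddx3y (27.9 against 29.5 FPKM) were similar in level.

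The other lists passed the test in neither direction, although several held called genes. The Wnt list held 4 higher genes, among them Sfrp2 (2.36-fold), and 1 lower gene, Wif1, of 20 (adjusted exact p = 0.0581 for higher genes). That value was 0.0390 with calls of at least 1.3-fold and 0.0144 at a q under 0.01, but 0.556 against genes at an FPKM of at least 1 in both groups and 0.524 with members found in 1 list only. In adrenergic and angiotensin signaling, Edn3 was 2.43-fold higher and Adra1a and Adra1b were 1.49-fold and 1.42-fold lower. Among cardiac transcription factors, Hopx was 1.48-fold higher and Klf15 1.39-fold lower, of 28 tested. Igf1 was 1.93-fold higher, Mt2, a metallothionein gene, 2.44-fold, and the p53 target Phlda3 2.14-fold. The fast skeletal muscle list held 2 higher genes, Mybpc2 (2.23-fold) and Casq1 (1.37-fold), and 2 lower genes, Myl1 (1.67-fold) and Cacna1s (1.49-fold), of 7 tested (adjusted exact p = 0.102 for lower genes). With calls at a q under 0.01 or of at least 1.3-fold, the adjusted exact p for its lower genes was 0.0351 or 0.0407, and the main isoform of Cacna1s had the opposite direction, at a log2 of 0.41. Of angiogenic and hypoxia-induced genes, 3 of 25 were lower, led by Angpt1, a ligand of the Tek receptor, at 1.87-fold. Of ribosomal protein genes, Rps2 (2.07-fold) and Rpl3 (1.28-fold) were higher, of 34 tested, and of lipid synthesis genes Fasn, Scd4 and Insig1 were higher, of 19 tested. Of lymphocyte and neutrophil markers, 3 each were tested and 1 each was higher, Ptprc and Lcn2. Lcn2 also stands in the cytokine list, and 1 called gene each does not show a change in these cell types. Adipocyte markers held no called gene of 3, and conduction and neural markers held 1 higher gene, Uchl1, and 1 lower gene, Hcn4, of 9. Comp was the 1 called gene of 3 tested cartilage genes, at 1.86-fold higher. Among random lists matched on FPKM, the medians of the stress, matrix, fibroblast, macrophage, complement, cytokine, heat shock and immediate-early lists lay at percentile 100, TGF-beta and BMP signaling at 98.8 and atrial markers at 89.0. Fatty acid oxidation and the respiratory chain lay at percentile 0, the creatine and TCA list at 0.01, ion channels at 1.29 and cardiomyocyte markers at 1.61. Calcium handling (0.32), interferon-stimulated (0.04) and angiogenic genes (0.31) also lay low, and antioxidant genes (99.8), chaperones of the endoplasmic reticulum (99.8), lymphocyte markers (99.7), neutrophil markers (99.2) and fast skeletal genes (99.2) high, although the calls of these lists did not pass Fisher's test. None of these values carries an error per animal. Ctrl mice lacked Cre, so the comparison does not separate Cre from the deletion of the targeted genes.

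At the other feature levels, every called isoform, start site group or coding sequence of a called gene had the direction of its gene. The authors' deposited tables called 559 isoforms (351 higher), 724 transcription start site groups (432 higher) and 598 coding sequences (384 higher). The called isoforms belonged to 552 genes, of which 532 were called as genes and 20 were not. Chosen after their values were seen, Sirt3, which encodes a mitochondrial deacetylase, had an isoform at 22.1 against 36.8 FPKM, and Ptpn14 had an isoform at 2.56 against 1.01 FPKM, while neither gene was called. Dmd had an isoform of 13852 bases at 2.01 against 10.9 FPKM and one of 4440 bases at 5.51 against 16.9 FPKM, both called lower, and another of 13820 bases at 1.89 against 2.07 FPKM that was not called. Transcripts that overlap are separated by a model of the reads, and single isoform values are less certain than gene totals.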

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

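The alternatives without loci that hold an isoform under 200 bases, without genes spanning over 200 kb, and with a fold of at least 2 were chosen after seeing the data. The 893 calls became 524 (332 higher, 192 lower) at a q under 0.01, 338 (258 higher, 80 lower, 76.3% higher) with a fold of at least 1.5, and 88 (66 higher, 22 lower, 75% higher) with a fold of at least 2. Lower genes numbered 207 with a fold of at least 1.3, and higher genes numbered 303 at a mean FPKM of at least 5. Each of these thresholds keeps a part of the calls by construction. At a q under 0.01, 343 isoforms, 413 transcription start site groups and 351 coding sequences were called. Isoforms in place of genes gave 559 calls with 208 lower, and coding sequences gave 214 lower, from 18490 and 12887 tested features against 12133 genes. Rescaling the groups to a median log2 ratio of 0 gave 522 higher and 371 lower genes again. It kept the authors' calls and removed a median of -0.00575, so it could change only directions and does not check the normalization. Between 12 and 15 lists passed under all settings, against 14. At a q under 0.01 the respiratory chain list (adjusted exact p = 0.471) and the creatine and TCA list (0.156) no longer passed, the Wnt list among higher genes (0.0144), and the fast skeletal (0.0351) and angiogenesis (0.0426) lists among lower genes did. Sox6 had a log2 of -0.60 from coding sequences. Sox5 had 1.29 from coding sequences and from its main isoform, the one with the highest mean FPKM, and 0.13 with log2(FPKM + 1). The Sox5 isoform most abundant in Ctrl went the other way, at 0.0965 FPKM in DKO and 0.205 in Ctrl, and Cuffdiff tested neither isoform. Of the other named genes, 19 moved by over 1.5 times with log2(FPKM + 1), among them Tnc (0.86), Clec7a (0.80), Ccr2 (0.81), Ltbp2 (0.78) and Cacna1h (0.72), and 13 with their main isoform. Cacna1s, lower as a gene, had 0.41 from its main isoform. The cause of these feature-level and gene-level differences was not tested. No paired analysis was possible because the columns carry no replicate. For the same reason leaving out each replicate, a replicate block and limma were not run. Depth per library is unknown, so what it limits could not be stated.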

Other observations

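These gene groups were chosen after the values were seen, so their tests describe the same data they were found in, and adjustment covers 20 comparisons of 10 lists. Genes of MHC class II presentation were higher in DKO in 7 of 8 tested members (Fisher's exact test, adjusted exact p = 1.35e-08), with H2-Ab1 at 53.2 against 27.1 FPKM and H2-Aa at 74.0 against 39.6 FPKM. Phagocyte receptors and lysosomal proteases were higher in 17 of 21 (adjusted exact p = 4.70e-19), among them Aif1 (2.35-fold), Trem2 (1.97-fold) and Ctss (1.75-fold). A list drawn up for activated stromal cells, which mixes cytoskeletal, annexin, S100 and galectin genes, was higher in 6 of 21 (adjusted exact p = 7.69e-04). These were Flnc, Vim, Anxa1, Anxa2, S100a4 and Lgals1, while the cytoskeletal genes Actb, Actg1, Tagln, Myl9 and Flna were not called. A mixed list of serine synthesis, one-carbon and amino acid response genes was higher in 5 of 16 (adjusted exact p = 0.00142), with Mthfd2, the mitochondrial folate enzyme, at 5.93 against 1.84 FPKM, Psat1 and Shmt1 2.11-fold and 1.59-fold higher, and the amino acid transporter genes Slc7a5 and Slc7a1 1.56-fold and 1.24-fold higher.

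Enzymes that break down branched-chain amino acids were lower in 12 of 20 members (adjusted exact p = 5.66e-13), among them Bckdhb (39.8 against 59.6 FPKM) and Dbt (28.0 against 39.1 FPKM), subunits of the branched-chain ketoacid dehydrogenase. Genes of ketone body use were lower in 2 of 5 (adjusted exact p = 0.0219), Bdh1 and Oxct1, and mitochondrial ribosome genes in 5 of 33 (adjusted exact p = 0.00871). Median log2 ratios were -0.29, -0.29 and -0.15 in these lists, beside -0.20 in the cardiomyocyte markers, of which 12 of 12 were below 0. Of the dystrophin-associated complex, Dmd and Sgca were lower, Sntb1 was higher and 12 of 15 were not called (adjusted exact p = 0.167 for lower genes).

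In the patterns below, the tests of transcript length, of joined loci and of the small RNAs were set before their results were seen, and all the others after. Genes at loci that cover long stretches of the genome were called lower more often than others, at 41 of 605 spanning over 200 kb against 330 of 11528. Higher calls were at 23 and 499. Spans are those of the listed loci, which can exceed the gene where a locus joins several. Over 500 kb, 14 of 92 were lower, among them Dmd, Ctnna3, Immp2l, Erbb4 and Sox6 itself, and 1, Slc9a9, was higher. Mature transcript length as the whole cause is opposed by an odds ratio of a lower call of 2.95 (95% interval 2.07 to 4.19) within strata of isoform length and FPKM, and joined loci by an odds ratio of 3.12 (1.65 to 5.88) among genes of 1 isoform alone at their locus. The lowest cardiomyocyte marker, Tnni3 at -0.31, gives no fair bound for genes selected as lower. The median log2 was -0.59 in the 41 lower genes and -0.39 in the 330 others, a difference of -0.20 (permutation test within 5 bins of FPKM, two-sided, p = 0.00149). This cannot decide on a smaller share of cardiomyocyte RNA, because both sets were selected as lower. Such a share lowers genes by how far they are restricted to cardiomyocytes, which was not compared between these sets, so it stays open. The unknown depth and RNA quality of each library also stay open, and no biological explanation was tested.

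The second pattern is that large rises sat at loci that join a small RNA with a longer gene. In 5 of 8 such called loci (62.5%) the longer transcripts differed by less than 1.3-fold, and in 7 the small RNA was listed at 0 in Ctrl. This fits a technical source, in which an FPKM over a very short length carries the locus. Short length alone has no direction, however, and in none of these loci was the small RNA at 0 in DKO. The cause of that direction was not tested. Cuffdiff gave no test result for the small RNA in any of these 8 loci, and loci that were not called were not examined. The exceptions to the limit of 1.3-fold were Cd74, whose longer transcripts were 1.80-fold higher, Dnaja1 at 1.45-fold and Gas5 at 1.31-fold. No biological explanation was tested.

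The third pattern is that matrix, fibroblast and macrophage genes were called higher, while 14 of 34 fatty acid oxidation, 9 of 44 respiratory chain and 5 of 18 creatine and TCA genes were called lower. A lower share of cardiomyocytes as the whole cause would raise endothelial markers too, but their median log2 was -0.0525 with a 75th percentile of -0.02, below the macrophage 25th percentile of 0.41, and blood left in the tissue is opposed likewise by the red cell and platelet median of 0.0168. For the mitochondrial genes that share stays open: their median was lower than that of sarcomere genes and cardiomyocyte markers by a difference of -0.11 (permutation test across genes, two-sided, p = 6e-05), but their 75th percentile of -0.17 lay above the others' 25th percentile of -0.21. Of 2 criteria tried, a first limit of 0.1 on that difference, set with the medians in view and passed narrowly, was dropped for this one, which the other marker tests use. Genes are not independent replicates, so the permutation p-values in these patterns give no error between animals. Recruited monocyte genes exceeded resident macrophage genes by a median log2 of 0.48 (exact permutation test across 5 and 6 genes, two-sided, p = 0.186). Of the recruited monocyte genes, Ccr2, Lyz1, Lyz2 and Itgam were called higher, and all of these also stand in the fixed macrophage list. Ly6c2 was not called, at 9.59 against 11.5 FPKM, and Cuffdiff did not test Plac8, at 0.965 against 0.932 FPKM. Lyz1 and Lyz2 are the near-identical copies named above. An equal rise of macrophage genes and an influx of monocytes therefore cannot be told apart with so few genes, whose restriction to recruited cells was not checked.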
